A study of Mus musculus with 12 samples.

How the data were processed

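RNA-seq was measured in 12 libraries of mouse alveolar macrophages, the resident macrophages of the air spaces, collected by lavage. The labels gave 6 groups of 2 libraries. Fresh cells came from wild-type and Vdr knockout mice at 10 and at 4 weeks of age. Wild-type cells were also cultured for 24 h without vitamin D3 or with 50 nM of it. Per the labels' protocols, RNA was extracted with a Qiagen RNeasy Micro kit and libraries were made with a KAPA mRNA HyperPrep kit. The labels do not say whether libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may in part be technical. At 10 weeks the 2 libraries of each genotype differed in sex by their Xist and Ddx3y levels, given below. They therefore came from different animals, and their spread includes any difference by sex.

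The authors deposited a table of raw counts per gene for 23413 genes, whose columns carry the library titles, so each column was matched to its sample without ambiguity. Per the submitters' processing notes, TopHat2, edgeR and the mouse build mm9 were used; their versions, the counting tool, its strand setting and the annotation are not given in the sources used here. The authors also deposited a log2 table of 10631 genes. Its values, taken back from the log2 scale and less a pseudocount of 1, sum to the same total in each column, so it holds log2(CPM + 1) over those genes with no scaling factor between libraries. The description code of 10-week knockout replicate 1 named wild type and that of 10-week wild-type replicate 2 named knockout, against their source names and genotype labels. The raw count columns took the genotype label, and the 4 columns of 10-week cells in the log2 table were used by the group their names state, without replicate numbers. Exchanging the pair of libraries in conflict was tried as an alternative.

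The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the deposited counts. TMM scaling was used, and genes were kept with filterByExpr on the groups (minimum count 10, minimum total count 15), which left 12748 genes. All 12 libraries entered 1 fit with 1 coefficient per group, which left 6 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. There were 7 contrasts: knockout against wild type at 10 weeks, at 4 weeks and over both ages, the genotype by age interaction, 10 against 4 weeks in each genotype, and vitamin D3 against none in culture. With 2 libraries against 2, a rank test cannot give a two-sided p under 0.333, and 33.3% of genes separate the groups without overlap by chance. CPM values are normalised counts scaled by TMM effective library sizes, and errors are SD over 2 libraries or the SE of a log2 fold change. Where a group held no more than 3 counts of a gene, a ratio of summed counts is given with its exact 95% interval, or a lower bound against 3 counts over the group. Such intervals cover counting error only.

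Before the data were examined, 30 gene lists were written (functions of macrophages, stress and metabolic pathways, vitamin D genes, neighbours of Vdr and markers of other cell types), and 27 had at least 5 tested members. They were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and again with an estimated correlation, with adjustment over the lists of a contrast. Genes called in 1 contrast were tested as a set in another by the same method, with adjustment over the sets of a contrast, which was applied after the unadjusted values had been seen. The contrasts, the alternatives and the rule for naming genes were fixed at the same time. The rule named Vdr and Cyp24a1, then up to 8 genes per direction with the largest log2 fold change among genes past the threshold whose groups did not overlap and whose higher group averaged at least 5 CPM, leaving out predicted genes and small RNAs. It also named up to 4 members with the smallest p of each list that passed or had at least 3 members past the threshold, and the 3 most abundant markers of each cell type list. For the interaction it took up to 5 genes per direction. Genes named outside the rule are said to be so.

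The same code was tested on simulated counts drawn from the group means, library sizes and dispersions of these libraries, with 200 genes changed. For knockout against wild type at 10 weeks, over 12547 genes, 60 of 100 genes changed 2-fold and 89 of 100 changed 4-fold were called, and 14 of 163 calls were unchanged genes. At 4 weeks, over 12580 genes, the shares were 61 and 85 of 100, with 10 of 156 calls unchanged. For vitamin D3, over 12575 genes, they were 62 and 75 of 100, with 9 of 146 calls unchanged.

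The alternatives were the Wald test of DESeq2 1.42.0, its size factors within the edgeR fit, no filter or a strict filter (5 CPM in 2 libraries), a fit on the groups of the contrast alone, the replicate number as a block (in culture the series of title numbers), that series as a covariate, limma-trend on the deposited log2 table, the label exchange and each library left out in turn. Sex as a covariate, the omission of both female libraries, and the list tests in those fits, with the replicate block and without 1 library in doubt were chosen after seeing the data. Coordinates are not printed, since the available reference (GRCm38) is another build than mm9; it was used only for the order of genes around Vdr, and 12694 tested genes (99.6%) were matched to it by name.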

Results

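The series measured gene expression in mouse alveolar macrophages, to ask how the vitamin D receptor (VDR) and its ligand act on these cells. It held 12 libraries in 6 groups of 2. Fresh cells came from wild-type and Vdr knockout mice at 10 and 4 weeks of age, and wild-type cells were cultured for 24 h without or with 50 nM vitamin D3. Total counts ranged from 10409572 (10-week knockout replicate 2) to 23233674 (vitamin D3 replicate 1), so 1 count was worth 0.0904 CPM or less. Replicates of each group differed by more than sampling noise, with chi-square values per degree of freedom from 10.1 to 54.0. Xist, the transcript of the inactive X chromosome, was at 800.3 and 787.3 CPM in replicate 2 of the 10-week wild type and knockout. In the other 10 libraries it was under 1 CPM, and the Y-linked Ddx3y was at 63.8 CPM or more. At 10 weeks the replicate number thus went with sex and with the series of title numbers, and was balanced between genotypes.

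Vdr, the targeted gene, was present in every library labelled knockout. At 10 weeks it was at 79.6 and 126.9 CPM in wild type and at 84.2 and 45 CPM in the libraries labelled knockout. At 4 weeks it was at 56.5 and 57.7 CPM in wild type and at 45.9 and 31.3 CPM in those labelled knockout. The log2 fold change was -0.66 ± 0.31 (SE) at 10 weeks (edgeR adjusted p = 0.538). At 4 weeks it was -0.56 ± 0.32 (edgeR adjusted p = 0.527), and over both ages -0.61 ± 0.22 (edgeR adjusted p = 0.261). With no filter on low counts it passed at 10 weeks, at 4 weeks and over both ages (edgeR adjusted p = 0.000141, 0.00308 and 5.14e-08), and in each of the other fits tried it did not. The 10-week library of replicate 1 labelled knockout held as much Vdr as wild type, with a log2 difference of 0.08 within replicate 1 and -1.49 within replicate 2. Its description code names wild type, against its source name and genotype label. The deposited log2 table, grouped by its own column names, gave a Vdr log2 fold change of -0.72 at 10 weeks. Exchanging the libraries in conflict gave 0.07. For Vdr, those column names thus go with the genotype labels and argue against the description codes. Genotypes are given below as the genotype label states them. Which part of the gene was removed is not given in the sources used here, so counts over the whole gene check the labels only in part. Cyp24a1, the vitamin D-degrading enzyme that VDR induces, had 0 to 2 counts in each fresh library, so a difference was not detectable at this depth. Of 18 known VDR targets, 0 passed at either age (camera adjusted p = 0.408 at 10 and 0.678 at 4 weeks). Of 14 genes of vitamin D metabolism and the receptor complex, 0 passed at either age (camera adjusted p = 0.275 and 0.974).

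**Figure D1:**
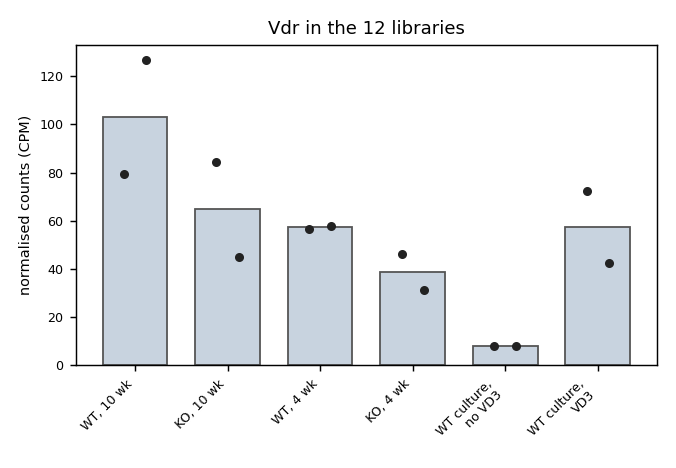
Normalised counts of Vdr (CPM on the vertical axis) in the 6 groups; bars are means and points are the 2 libraries of each group. The 10-week library of replicate 1 labelled knockout (84.2 CPM) lies between both wild-type libraries of that age, and untreated cultured cells lie lowest (7.82 and 7.61 CPM).

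At 10 weeks, Ager, a marker of type I alveolar epithelium, averaged 10.2 ± 0.743 CPM (SD, n = 2) in the libraries labelled knockout and 2 ± 0.53 CPM in wild type. Its log2 fold change was 2.37 ± 0.30 (edgeR adjusted p = 0.0147). Il15ra, a receptor chain for interleukin 15, was 2.32-fold higher and the tubulin gene Tuba1c 2.22-fold. The toll-like receptor gene Tlr13 was 1.88-fold higher and the metal transporter gene Slc11a2 1.76-fold. Gpcpd1 was 1.92-fold higher and Cd300lf 1.67-fold. Arl4c, a small GTPase gene, had a log2 fold change of -1.61 ± 0.21, the myosin gene Myo5a of -1.48 ± 0.16 and Scd2, a fatty acid desaturase gene, of -1.16 ± 0.19. Within replicate 1 (male) and replicate 2 (female), Ager differed by log2 2.49 and 2.12, Myo5a by -1.51 and -1.44, and Scd2 by -1.59 and -0.80. In all, 14 of 12748 genes changed, 11 higher and 3 lower, and 1244 had an unadjusted p under 0.05. The predicted genes Gm6682, Gm17757 and Gm4980, named here after their values were seen, were among the 11 higher ones.

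All 14 tested heat shock genes had lower values in the 10-week libraries labelled knockout. None passed over all genes, and 10 passed adjusted over the list alone. The chaperone genes Hspa1b and Hspa1a had log2 fold changes of -3.37 ± 0.62 and -3.61 ± 0.67 (edgeR adjusted p = 0.0789 and 0.0791). The list passed camera with the preset correlation (adjusted p = 4.63e-18) but not with an estimated one (adjusted p = 0.112 with an estimated correlation). Lists of markers of other cell types also passed with the preset correlation alone. T cell markers had lower values for 12 of 12 members, 0 past the threshold and 2 adjusted over the list alone (camera adjusted p = 3.54e-08, and adjusted p = 0.168 with an estimated correlation). Dendritic cell markers had lower values for 11 of 13, with 0 past the threshold and 5 adjusted over the list alone (camera adjusted p = 1.21e-05, and adjusted p = 0.178 with an estimated correlation). Of 20 epithelial markers, Ager alone passed, and 6 passed adjusted over the list alone (camera adjusted p = 0.000481, higher, and adjusted p = 0.178 with an estimated correlation). In untreated culture Ager was at log2 -0.0055 ± 0.32 against fresh wild type at 10 weeks and -0.83 ± 0.31 at 4 weeks. Of the 20 markers, 10 were lower there than at both ages and 0 were higher. The cell of origin of Ager was not tested, so its rise is not read as more epithelium.

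Interferon-stimulated genes (camera adjusted p = 5.66e-06), monocyte and interstitial macrophage markers (0.0102) and erythroid genes (0.0149) leaned lower at 10 weeks, and TGF-beta genes (0.0149) leaned higher. With an estimated correlation the adjusted p of these lists were 0.145, 0.178, 0.207 and 0.207. Among 25 listed genes near Vdr on chromosome 15, 1 was higher, Tuba1c (camera adjusted p = 0.0658). The count of changed genes was 1 without wild-type replicate 1, 1 without wild-type replicate 2, 71 without the library of replicate 1 labelled knockout and 5 without that of replicate 2. None of the 10 named genes passed in all 4 of these fits, with Ager reaching an edgeR adjusted p of 0.224. The count was 39 with the replicate number as a block, and, in fits chosen after seeing the data, 24 with sex as a covariate and 2 without both female libraries. Exchanging both libraries with conflicting labels gave 6, with 0 of the 14 genes shared, and turned Tuba1c, Slc11a2, Gpcpd1 and Scd2 in direction. Each side then held 1 library of each genotype label, so differences by label shrank by design and this loss does not test them. Omitting both female libraries left 1 library per 10-week group, with replicate 1 as the only library labelled knockout.

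At 4 weeks, Hmox1, the haem-degrading oxygenase, averaged 988 ± 3.91 CPM (SD, n = 2) in knockout and 191.8 ± 56 CPM in wild type, a log2 fold change of 2.37 ± 0.19 (edgeR adjusted p = 0.000112). Me1, the NADPH-producing malic enzyme, rose by log2 3.54 ± 0.36, and the ferritin genes Ftl1 and Fth1 by 1.01 ± 0.11 and 0.95 ± 0.12. Slc40a1, the cellular iron exporter ferroportin, rose by 2.33 ± 0.28 (edgeR adjusted p = 0.00266). Of 20 tested members of the NRF2 antioxidant list, 7 rose, 0 fell and 13 did not pass, and 17 rose adjusted over the list alone. The list passed camera with the preset correlation (adjusted p = 3.89e-40) and with an estimated one (adjusted p = 0.0222 with an estimated correlation). The scavenger receptor gene Marco rose by log2 2.25 ± 0.31, Ear5 by 2.69 ± 0.48, Tsku by 3.93 ± 0.52 and Slc36a2 by 4.41 ± 0.68. Among genes that fell were Id3, an inhibitor of helix-loop-helix transcription factors (log2 -2.40 ± 0.38), and the erythroid haem synthesis gene Alas2 (-2.13 ± 0.41). The protease inhibitor gene Slpi (-1.43 ± 0.14) and the growth arrest gene Btg2 (-1.12 ± 0.17) also fell.

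**Figure D2:**
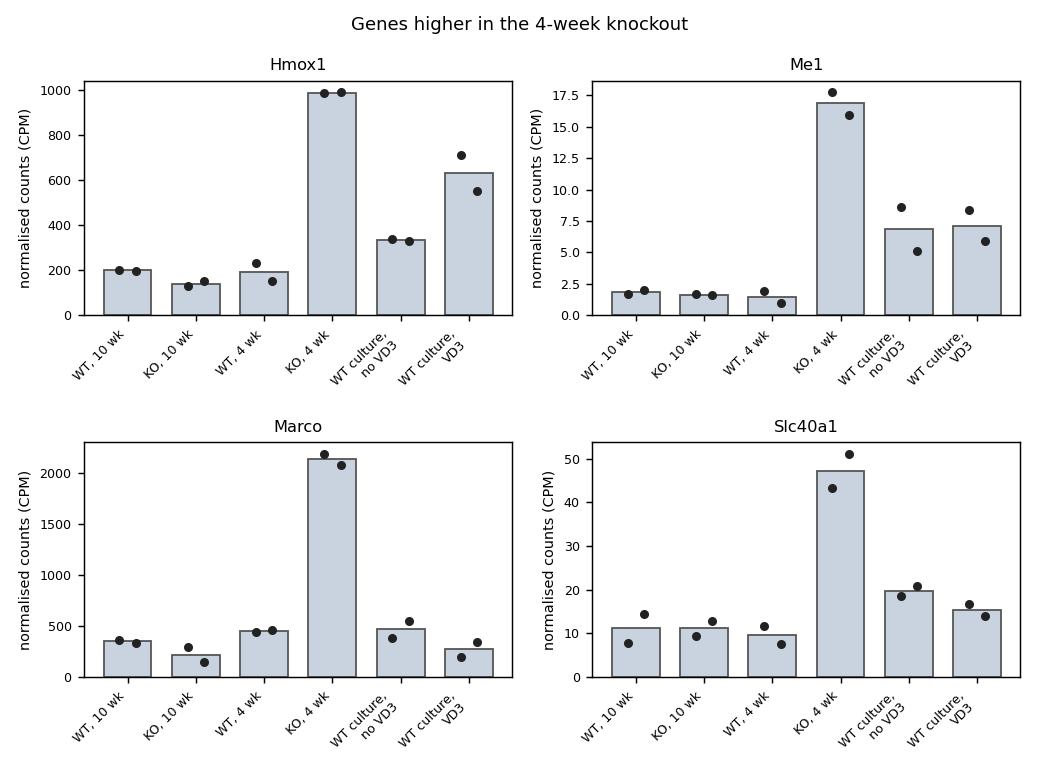
Normalised counts (CPM on the vertical axes) of Hmox1, Me1, Marco and Slc40a1 in the 6 groups; bars are means and points the 2 libraries of each group. For each gene both 4-week knockout libraries lie above all other fresh libraries, for Hmox1 at 985.3 and 990.8 CPM.

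Other lists passed at 4 weeks with the preset correlation. All 21 immediate early genes had lower values in knockout, of which 2 fell, Btg2 and Jund, and 7 adjusted over the list alone (camera adjusted p = 1.57e-13, and adjusted p = 0.216 with an estimated correlation). Cell cycle genes had higher values for 32 of 33 members, 0 past the threshold and 7 adjusted over the list alone (camera adjusted p = 1.16e-13, and adjusted p = 0.506 with an estimated correlation). All 8 erythroid genes had lower values, with 1 past the threshold, Alas2, and 6 adjusted over the list alone (camera adjusted p = 1.62e-08, and adjusted p = 0.0701 with an estimated correlation). Hba-a1, a haemoglobin gene, was at 2315 and 884.8 CPM in wild type and at 227.8 and 488.7 CPM in knockout. Dendritic cell markers had lower values for 12 of 13 members (camera adjusted p = 1.87e-05, and adjusted p = 0.261 with an estimated correlation). T cell markers did for 10 of 12, of which Cd2 passed (camera adjusted p = 0.0166, and adjusted p = 0.554 with an estimated correlation). In untreated culture Cd2 held its level (log2 -0.12 ± 0.11 against fresh wild type at 10 weeks and 0.19 ± 0.11 at 4 weeks). Of the 12 markers, 3 were lower there than at both ages and 1 was higher. The cell of origin of Cd2 was not tested, so its fall is not read as fewer T cells. The 3 tested endothelial and stromal markers, too few for camera, had higher values in knockout (median log2 1.71), 0 past the threshold and 3 adjusted over the list alone. Of these, Acta2 was at 2.17 and 1.16 CPM in wild type and at 4.65 and 6.10 CPM in knockout. MHC class II genes leaned lower, and cholesterol synthesis, lysosome and glycolysis genes higher, with no member past the threshold. Their camera adjusted p were 2.92e-05, 1.36e-05, 0.0234 and 0.0453, and with an estimated correlation the adjusted p were 0.447, 0.554, 0.577 and 0.834. Among the 25 listed genes near Vdr, 1 was higher, Tuba1c (camera adjusted p = 0.683).

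In all, 85 genes changed at 4 weeks, 60 higher and 25 lower. Amd1 had the largest fitted change among named genes, but it may share reads with the near-identical copy Amd2, so its change is uncertain. It held 3 counts over both wild-type libraries and 3413 over both knockout libraries, a ratio of 1230 with an exact counting interval of 421 to 5980. Amd2 was at 97.7 and 113.6 CPM in wild type and at 8.25 and 0.0701 CPM in knockout. The count of changed genes was 34 without wild-type replicate 1, 34 without wild-type replicate 2, 26 without knockout replicate 1 and 30 without knockout replicate 2. Hmox1, Me1, Ftl1, Slc40a1, Slpi and Amd1 passed in each of these 4 fits, and the other 15 named genes lost their call in at least 1 of them. Marco, for example, reached an edgeR adjusted p of 0.0878. With the replicate number as a block the count was 146, and with the 10-week label exchange in the shared fit it was 42. It was larger still with DESeq2, with only the compared groups in the fit and without a filter (690), as given below.

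**Figure D3:**
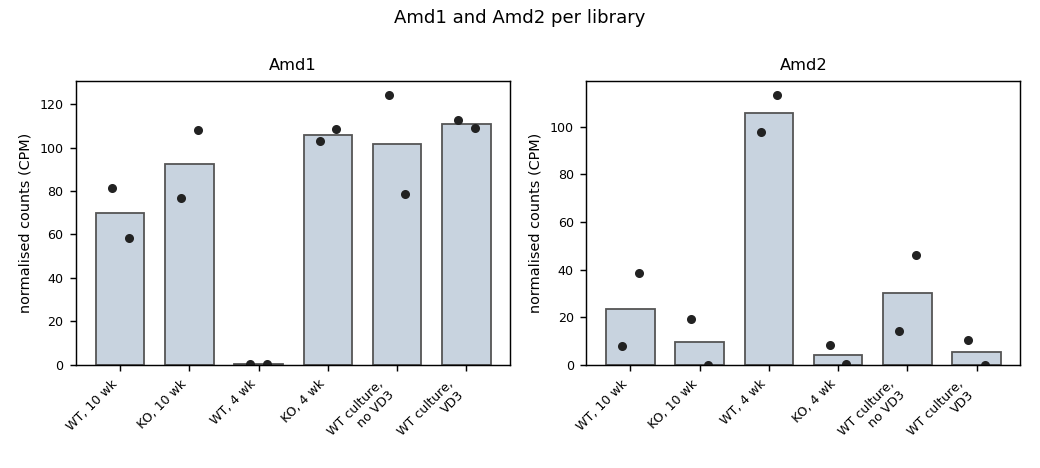
Normalised counts (CPM on the vertical axes) of the near-identical copies Amd1 and Amd2 in the 6 groups; bars are means and points the 2 libraries of each group. Both 4-week wild-type libraries hold Amd2 (97.7 and 113.6 CPM) and nearly no Amd1.

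Over both ages, with 4 libraries per genotype, 127 genes changed, 78 higher and 49 lower. Tuba1c was higher by log2 1.20 ± 0.13 (edgeR adjusted p = 0.00253) and Klhl6 by 1.21 ± 0.13 (edgeR adjusted p = 0.00275). Lrg1, Ear6, Cspg4 and Cd200r2 rose by 1.88 ± 0.37, 1.73 ± 0.30, 1.47 ± 0.28 and 1.21 ± 0.21 on the log2 scale. The glucocorticoid-responsive gene Fkbp5 rose by 1.15 ± 0.18 and Rgcc by 1.12 ± 0.20. Id3 had a log2 fold change of -2.50 ± 0.32, Hspa1a of -2.64 ± 0.47, the dendritic cell genes Fscn1 and Ccl22 of -2.12 ± 0.40 and -1.52 ± 0.29, and Arl4c of -1.22 ± 0.15. Of 20 NRF2 genes 6 rose and 0 fell, 13 adjusted over the list alone (camera adjusted p = 1.44e-19, and adjusted p = 0.0713 with an estimated correlation). At 10 weeks by itself 0 of the 20 passed, with 9 higher and 11 lower values (camera adjusted p = 0.955), so this average rests on the 4-week libraries. Of 21 immediate early genes 4 fell, 8 adjusted over the list alone (camera adjusted p = 2.66e-08, and adjusted p = 0.181 with an estimated correlation), while at 10 weeks by itself the list did not pass (camera adjusted p = 0.364). Of 13 dendritic cell markers 3 fell, 6 adjusted over the list alone (camera adjusted p = 1.51e-08, and adjusted p = 0.113 with an estimated correlation). In all, 15 of 27 lists passed with the preset correlation and 0 with an estimated one.

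The 11 genes higher at 10 weeks leaned higher at 4 weeks as a set, in separate libraries, with 8 of 11 positive (camera adjusted p = 3.09e-14, and adjusted p = 0.00119 with an estimated correlation). Of them, 4 were also called higher at 4 weeks, where independent lists would share 0.0518 (Fisher's exact test, two-sided p = 1.43e-07). Both contrasts took the spread of each gene from the same fit, so their calls are not fully independent and the expected number may be too low. The 4 genes were Tuba1c, Slc11a2, Tlr13 and Gm6682, named after their values were seen. Tuba1c and Slc11a2 lie 20 and 41 tested genes from Vdr on chromosome 15. A chromosome segment linked to Vdr, a hypothesis taken up below, could recur at both ages, so their overlap cannot be assigned to loss of VDR. Of the 3 called lower, 0 were shared, and only 1 had a lower value at 4 weeks. The 50 lower genes with the smallest p leaned lower at 4 weeks (camera adjusted p = 0.00892, and adjusted p = 0.266 with an estimated correlation). Over both ages the count of changed genes was 25 and 56 without 10-week wild-type replicates 1 and 2, and 68 without 10-week knockout replicate 2. It was 30 and 64 without 4-week wild-type replicates 1 and 2, and 22 and 30 without 4-week knockout replicates 1 and 2. Without the 10-week library of replicate 1 labelled knockout it was 189, and with the replicate block 200. It was 29 with the label exchange and 41 without both female libraries, a fit chosen after seeing the data. Klhl6, Tuba1c, Id3, Arl4c and Hmox1 passed in all 8 fits that left out a library, and the other 21 named genes did not. For Hmox1, the 10-week minus the 4-week knockout difference was log2 -2.87, larger in size than its rise at 4 weeks. Its average over both ages thus rests on the 4-week libraries.

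The knockout difference itself depended on age for 24 genes, 8 with a higher value at 10 weeks and 16 with a lower one. Hmox1 differed by log2 -2.87 ± 0.26 (edgeR adjusted p = 0.000706), Me1 by -3.70 ± 0.52, Marco by -2.94 ± 0.43 and the lipid phosphatase gene Ppap2b by -3.02 ± 0.27. In the other direction, Ager differed by 2.82 ± 0.42, Tppp3 by 1.49 ± 0.24 and the growth factor gene Pdgfc by 1.40 ± 0.19. The inhibitory receptor gene Lair1 differed by 1.20 ± 0.20 and Gpcpd1 by 1.15 ± 0.17. Of 20 NRF2 genes, 3 had a lower difference at 10 weeks, 14 adjusted over the list alone (camera adjusted p = 5.64e-26, and adjusted p = 0.0717 with an estimated correlation). For Hmox1, Me1, Marco and this list, the interaction uses the same 4-week knockout libraries as the rise at 4 weeks and is not independent of it. The count was 6 and 6 without 10-week wild-type replicates 1 and 2, and 13 and 14 without 10-week knockout replicates 1 and 2. It was 11 and 8 without 4-week wild-type replicates 1 and 2, and 6 and 5 without 4-week knockout replicates 1 and 2. It was 12 with the label exchange and 8 without both female libraries. Hmox1, Ppap2b and Amd1 passed in all 8 of these fits, while Ager and Lair1 passed in 0 of them (highest edgeR adjusted p = 0.172 and 0.285).

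Between 4 and 10 weeks in wild type, Ciita, the class II transactivator, rose by log2 3.89 ± 0.34 (edgeR adjusted p = 0.000534), H2-Ab1 by 4.01 ± 0.57, H2-Eb1 by 3.74 ± 0.52 and the invariant chain gene Cd74 by 4.15 ± 0.67. Of 13 class II genes, 6 rose and 0 fell, and 9 rose adjusted over the list alone (camera adjusted p = 3.53e-18, and adjusted p = 0.0693 with an estimated correlation). Hba-a1 fell by 5.38 ± 0.55 and Hbb-b1 fell by 3.64 ± 0.42 on the log2 scale. Of 8 erythroid genes, 4 fell, 7 adjusted over the list alone (camera adjusted p = 1.72e-16, and adjusted p = 0.0397 with an estimated correlation). The epithelial adhesion gene Epcam rose by log2 2.52 ± 0.36 and the dendritic cell receptor gene Clec9a by 2.72 ± 0.34, while the scavenger receptor gene Msr1 had a log2 fold change of -1.86 ± 0.24. The chaperone genes Dnaja1, Chordc1 and Dnajb1 rose, 3 of 14 on the heat shock list (camera adjusted p = 8.85e-05, and adjusted p = 0.457 with an estimated correlation). Of 33 cell cycle genes, 1 fell, Cdc20, and 5 adjusted over the list alone (camera adjusted p = 6.91e-10, and adjusted p = 0.577 with an estimated correlation).

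In all, 269 genes changed with age in wild type, 179 higher and 90 lower. Oxidative phosphorylation genes leaned lower (camera adjusted p = 0.00082, and adjusted p = 0.744 with an estimated correlation). Interferon-stimulated genes leaned higher (camera adjusted p = 0.00651, and adjusted p = 0.457 with an estimated correlation). The genes of vitamin D metabolism and the receptor complex leaned higher as well (camera adjusted p = 0.0496, and adjusted p = 0.577 with an estimated correlation). The count was 58 and 150 without 10-week replicates 1 and 2, and 63 and 68 without 4-week replicates 1 and 2. Of 29 named genes, 13 passed in each of these fits. Cd74 lost its call without 10-week replicate 1 (edgeR adjusted p = 0.0554), and Dnaja1, Chordc1, Dnajb1 and Cdc20 lost theirs in at least 3 of the 4 fits.

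In the libraries labelled knockout, 1240 genes changed between 4 and 10 weeks, 624 higher and 616 lower. Ciita rose by log2 5.75 ± 0.39 (edgeR adjusted p = 2.29e-05), H2-Ab1 by 6.11 ± 0.64 and Cd74 by 6.11 ± 0.74. Of 13 class II genes, 9 rose, 10 adjusted over the list alone (camera adjusted p = 7.77e-24, and adjusted p = 0.0707 with an estimated correlation). Of 33 cell cycle genes, 29 fell, among them Ccnb1 (log2 -1.49 ± 0.20), and 33 adjusted over the list alone (camera adjusted p = 7.77e-30, and adjusted p = 0.208 with an estimated correlation). Of 20 NRF2 genes, 13 fell, with Hmox1 at -2.81 ± 0.19 and Me1 at -3.35 ± 0.35, and 17 adjusted over the list alone (camera adjusted p = 3.93e-20, and adjusted p = 0.0707 with an estimated correlation). In wild type the median of this list changed by log2 -0.000967 with age. The knockout fall rests on the same 4-week knockout libraries as the 4-week rise and the interaction, so these are not separate findings. Of 8 erythroid genes, 3 fell (camera adjusted p = 1.22e-06, and adjusted p = 0.0922 with an estimated correlation). Marco had a log2 fold change of -3.31 ± 0.33, Hba-a1 of -4.14 ± 0.53, Epcam of 3.74 ± 0.38 and Timp2, an inhibitor of metalloproteinases, of 2.21 ± 0.26. Immediate early genes leaned higher (camera adjusted p = 0.000395, and adjusted p = 0.643 with an estimated correlation) and oxidative phosphorylation genes lower (camera adjusted p = 0.00132, and adjusted p = 0.792 with an estimated correlation).

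Fbp1, the gluconeogenic phosphatase, held 1 count at 10 weeks and 1360 at 4 weeks in knockout, a ratio of 1330 with an exact counting interval of 238 to 52500. It lost its call without either 10-week library or without 4-week replicate 2 (highest edgeR adjusted p = 0.205). The age changes of both genotypes, which share no library, overlapped. In both, 119 genes were called higher, where independent lists would share 8.76, and 57 lower, where they would share 4.35. As the spread of each gene came from the same fit, these expected numbers may be too low. In both genotypes the 4-week libraries were male and of 1 title series, while the 10-week ones held 1 female library and 1 of the other series. The shared changes therefore cannot be assigned to age alone. The knockout count was 664 and 625 without 10-week replicates 1 and 2, 481 and 236 without 4-week replicates 1 and 2, and 781 with the replicate block. It was 821 with the label exchange and 535 without both female libraries. Of 65 named genes, 35 passed in each of the 4 fits that left out a library.

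In culture, vitamin D3 raised its own receptor and its degrading enzyme. Cyp24a1 was at 484.8 and 215.6 CPM with vitamin D3 and at 0.383 and 0.243 CPM without, a log2 fold change of 10.04 ± 0.53 (edgeR adjusted p = 1.59e-05). Vdr rose by log2 2.89 ± 0.36 (edgeR adjusted p = 0.000433). Hbegf, a growth factor of the EGF family, averaged 103.7 ± 33.5 CPM (SD, n = 2) with vitamin D3 and 0.421 ± 0.0232 CPM without, a log2 fold change of 7.91 ± 0.43. The vascular growth factor gene Vegfa rose by log2 5.64 ± 0.39, the stress gene Gadd45a by 3.23 ± 0.22, Foxf2 by 5.93 ± 0.61 and Nxph3 by 6.16 ± 0.71. Gsta2, a glutathione transferase gene, had 393 counts with vitamin D3 and 0 without and was at least 116-fold higher (against 3 counts over the group). Mdfi had 850 counts and 1, a ratio of 753 with an exact counting interval of 135 to 29800. Gpr34 had a log2 fold change of -4.25 ± 0.39, the matrix gene Tgfbi of -3.61 ± 0.54, Kazald1 of -2.86 ± 0.35, the metalloproteinase gene Mmp14 of -2.49 ± 0.48 and Mcam of -2.30 ± 0.30. In all, 1356 genes changed, 638 higher and 718 lower.

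Of 18 known VDR targets, 6 rose and 2 fell, 7 and 4 adjusted over the list alone (camera adjusted p = 4.7e-07, and adjusted p = 0.0239 with an estimated correlation). Of 27 phagocytic and scavenger receptor genes, 7 fell, among them the Fc receptor gene Fcgr1 (log2 -2.06 ± 0.28), and 3 rose, among them the lipid scavenger gene Cd36 (1.49 ± 0.13). The list leaned lower (camera adjusted p = 0.00665, and adjusted p = 0.145 with an estimated correlation). Of 30 lipid handling genes, 9 fell and 2 rose, Cd36 and the triglyceride synthesis gene Dgat1 (2.05 ± 0.20), and the list leaned lower (camera adjusted p = 0.011, and adjusted p = 0.145 with an estimated correlation). Of 13 MHC class II genes, 4 fell, among them H2-DMa (-0.80 ± 0.14), and 7 adjusted over the list alone (camera adjusted p = 0.00356, and adjusted p = 0.593 with an estimated correlation). Of 30 genes of alveolar macrophage identity, 6 rose, among them Car4 (3.24 ± 0.26) and Ccl6 (2.22 ± 0.17), and 7 fell, among them Il18 (-1.06 ± 0.14), and the list did not pass (camera adjusted p = 0.662). The macrophage growth factor receptor gene Csf1r fell by 1.29 ± 0.19 on the log2 scale. Glycolysis and hypoxia genes leaned higher with 3 of 24 past the threshold, among them Vegfa and Ldha (camera adjusted p = 0.00422, and adjusted p = 0.882 with an estimated correlation).

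Cell cycle genes (camera adjusted p = 0.00143), oxidative phosphorylation genes (0.00143) and unfolded protein response genes (0.011) leaned higher with vitamin D3, with 1 member of each past the threshold. With an estimated correlation the adjusted p of each of these lists was 0.882. Interferon-stimulated genes (camera adjusted p = 0.011), monocyte and interstitial macrophage markers (0.032) and cholesterol synthesis genes (0.0366) leaned lower, with 2, 3 and 1 members past the threshold. With an estimated correlation their adjusted p were 0.499, 0.499 and 0.882. The count of changed genes was 823 without untreated replicate 1, 1164 without untreated replicate 2, 547 without vitamin D3 replicate 1 and 1350 without vitamin D3 replicate 3. Of 74 named genes, 44 passed in each of these 4 fits, Cyp24a1, Vdr, Hbegf and Vegfa among them. Mmp14 lost its call without untreated replicate 1 or vitamin D3 replicate 1 (highest edgeR adjusted p = 0.0877).

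The 638 genes raised by vitamin D3 in culture were not found to differ as a set in the fresh knockout contrasts (camera adjusted p = 0.394 at 10 weeks and adjusted p = 0.1 at 4 weeks). Nor were the 718 lowered genes (camera adjusted p = 0.394 and adjusted p = 0.437). With the 50 raised genes of smallest p in place of the called ones, the set leaned higher in knockout at 4 weeks (camera adjusted p = 0.0184).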

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

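The interaction test was planned, and all tests of explanations in this part were chosen after the results were seen. The knockout difference changed between 4 and 10 weeks, by a test of the interaction, for 10 named genes and 6 gene lists, which is what drew attention to them. As the 10-week minus the 4-week knockout difference on the log2 scale, these were Ager 2.82, Tppp3 1.49, Pdgfc 1.40, Lair1 1.20, Gpcpd1 1.15, Amd1 -9.75, Me1 -3.70, Ppap2b -3.02, Marco -2.94 and Hmox1 -2.87. The list medians were -0.84 for NRF2 genes, -0.68 for cell cycle genes, -0.66 for heat shock genes, -0.14 for lipid handling genes, 0.79 for immediate early genes and 0.56 for MHC class II genes. With an estimated correlation the adjusted p of these 6 lists were 0.0717, 0.431, 0.21, 0.21, 0.399 and 0.399, so none passed.

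NRF2 genes were higher as a list in knockout at 4 weeks. Erythroid RNA carried over with the knockout cells is argued against, since the erythroid list had a median log2 fold change of -2.1 in the knockout. Library scaling moves all genes alike, and the NRF2 median lay 0.897 above that of the other tested genes (SE 0.216). TMM scaling holds the median of the other genes near 0 (-0.00706), so this difference is close to the list median itself (0.889). It is therefore no separate test of scaling. A stricter bound set first, over 0.5 by more than 2 SE, was missed. A general stress of handling was not decided: heat shock, immediate early and unfolded protein response genes had a median of -0.178 with 45 of 55 lower, but only the immediate early list passed (camera adjusted p = 1.57e-13, and adjusted p = 0.216 with an estimated correlation), against camera adjusted p = 0.759 for heat shock and 0.221 for unfolded protein response genes. The genotype at 4 weeks stays open as a hypothesis, as do unlabelled differences in litter or housing, which were not tested.

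Amd1 was nearly absent in both 4-week wild-type libraries and abundant elsewhere. Reads shared with its near-identical copy may account for this: the sum of Amd1 and Amd2 differed by only 0.0572 on the log2 scale between 4-week knockout and wild type. No biological explanation was tested. A strain difference at these copies, or a difference in how reads were assigned, stays open.

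The 10-week library of replicate 1 labelled knockout had Vdr at the wild-type level, and its description code names wild type, while that of wild-type replicate 2 names knockout. The column names of the deposited log2 table went with the genotype labels for Vdr (log2 -0.72 at 10 weeks, against 0.07 with the exchange). Whether the replicate 1 library is a wild-type library under a wrong label was asked of the genes around Vdr that differed at 4 weeks. Along that difference, over 7 genes, it scored 0.643, against 0.76 for the other 10-week library labelled knockout. On this scale 0 is the wild-type mean and 1 the full 4-week difference. The wild-type libraries scored 0.0307 and -0.0307, opposite by construction since their mean sets 0, which shows only that they resemble each other. Tuba1c and Slc11a2, among the 7 genes, had already been called at 10 weeks when this index was chosen. RNA from epithelium as a source of Vdr cannot be told apart from a difference between animals, since epithelial markers had a median log2 ratio of 0.506 between both 10-week libraries labelled knockout but only 14 of 20 were higher. Transcript kept from the targeted allele, or a heterozygous animal, stays open and was not tested.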

How the results depend on the processing

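Fits with sex as a covariate or without both female libraries were chosen after seeing the data, as were list tests with the replicate block, with sex or without the 10-week knockout replicate 1. Outcomes of these list tests are not given here, so whether the 10-week list results hold without that library is left open. Counts of changed genes are given in the order knockout at 10 weeks, at 4 weeks, over both ages, interaction, age in wild type, age in knockout and vitamin D3. They stayed within 1.5 times in all 7 comparisons with median-ratio size factors, a strict filter or the deposited log2 values. DESeq2 gave 149, 261, 369, 89 and 676 for the first 5. Without a filter, the first 6 gave 503, 690, 791, 392, 1223 and 2059. Nearly all of these lay among genes that the filter keeps (502 of 503 at 10 weeks), while the prior degrees of freedom of the fit went from 5.57 to no finite value. Vdr then passed at 10 weeks (-0.67, edgeR adjusted p = 0.000141), against adjusted p from 0.204 to 1 in its other fits. With only the groups compared in the fit, counts were 30, 656, 280, 53 and 583, and 708 with vitamin D3. A block for the replicate number gave 39, 146 and 200, and 781 for age in knockout. The labels do not say that it pairs fresh samples, and deviations of same-numbered libraries from their group means correlated at 0.122 at 10 weeks and -0.119 at 4 weeks. In culture only number 1 (source name WT1) was in both arms, so the block there was the title series, with a correlation of 0.272. The title series gave 52, 162, 251 and 40, and sex 24 at 10 weeks. The cause was not tested for these settings.

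Exchanging the pair of libraries with conflicting labels gave 6, 42, 29 and 12, and 821 for age in knockout, with 0 of 14 genes shared at 10 weeks. At 10 weeks it turned Vdr to 0.073, Tuba1c to -0.015, Gpcpd1 to -0.19, Slc11a2 to -0.061 and Scd2 to 0.15, and the Vdr interaction to 0.64. The exchange puts 1 library of each genotype label on each side at 10 weeks. The loss of the 14 genes and the small values there were thus built in. Without both female libraries, counts were 2 at 10 weeks, 41 over both ages, 8 for the interaction and 535 for age in knockout. Vdr was then 0.082 at 10 weeks and its interaction 0.65. This design left 1 library in each 10-week group, with replicate 1, the library in doubt, as the only one labelled knockout. Its 10-week Vdr value is therefore the difference within replicate 1, and sex cannot be told apart from that library. Leaving out each library in turn, with a lone library assumed to vary like the other groups, gave 1 to 71, 26 to 34, 22 to 189, 5 to 14, 58 to 150, 236 to 664 and 547 to 1350. Values of single genes kept their direction and side of the threshold in 684 of 1116 such fits, 429 lost the call and 3 turned, those of the Vdr interaction, which went from -0.63 to 0.27. With an estimated correlation, lists passing fell to 0, 1, 0, 0, 1, 0 and 1, from 8, 10, 15, 6, 7, 6 and 11. The set of 10-week lower genes at 4 weeks then had adjusted p = 0.266, while with the preset correlation the 50 strongest vitamin D3-raised genes had camera adjusted p = 0.0184 at 4 weeks. Genes at 0 counts in a group have no finite fold, and differences under 3 counts were not detectable.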

Other observations

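The tests in this part were chosen after the results were seen, except the count of other splits. Untreated cultured macrophages differed widely from fresh wild-type cells: 3985 genes differed the same way from both ages, 2027 higher and 1958 lower in culture. The ages of the mice behind the cultures are not in the labels, and culture cannot be separated here from other differences in handling. Of 20 NRF2 genes 18 were higher than at both ages (camera adjusted p = 9.66e-13 against 10 weeks, and adjusted p = 0.14 with an estimated correlation), as were 28 of 30 lysosomal genes (camera adjusted p = 5.23e-21, and adjusted p = 0.0833 with an estimated correlation) and 20 of 21 cholesterol synthesis genes (camera adjusted p = 8.92e-17, and adjusted p = 0.227 with an estimated correlation). Of 33 cell cycle genes 30 were lower (camera adjusted p = 8.92e-17, and adjusted p = 0.293 with an estimated correlation). Some markers of other cell types were lower in culture. Of 20 epithelial markers 10 were lower than at both ages (camera adjusted p = 0.00365 against 10 and 0.00173 against 4 weeks, and adjusted p = 0.3 and 0.253 with an estimated correlation). Of 8 erythroid genes 4 were (camera adjusted p = 0.00275 and 7.29e-08, and adjusted p = 0.228 and 0.085 with an estimated correlation). Of 13 dendritic cell markers 5 were (camera adjusted p = 0.00473 and 0.0515, and adjusted p = 0.3 and 0.525 with an estimated correlation). Monocyte and interstitial macrophage markers, 5 higher and 1 lower of 17, did not pass (camera adjusted p = 0.616 and 0.295), nor did the T cell and neutrophil lists, and 2 of 3 endothelial and stromal markers were higher. Vdr was at 7.82 and 7.61 CPM in untreated culture, below each of the 8 fresh libraries, the lowest of which was at 31.25 CPM.

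Genes called in the knockout over both ages were more frequent in a wide window around Vdr than elsewhere. Among the 50 tested genes on each side of Vdr on chromosome 15 (by the gene order of GRCm38), 4 of 100 were called, Tuba1c, Slc11a2, Gpd1 and Smarcd1, against 122 of 12593 other genes, an odds ratio of 4.26 with a 95% interval of 1.12 to 11.5 (Fisher's exact test, two-sided p = 0.0175). A chromosome segment from the strain in which the gene was targeted may account for these genes, as a hypothesis found and tested on the same data; the strain is not in the labels. All 4 lay on 1 side of Vdr, with 0 on the other, and none of the 19 nearest genes on each side was called. Among these nearest genes, Adcy6, Cacnb3 and Fkbp11 came close, with log2 fold changes of -1.71, -1.91 and -2.95 (edgeR adjusted p = 0.0659, 0.0742 and 0.0668). Each had an unadjusted p under 0.05 at both ages. Tuba1a was higher by log2 1.06 (edgeR adjusted p = 0.13). The list of neighbours fixed before the data were examined had 1 of 25 called and did not pass (camera adjusted p = 0.114, and adjusted p = 0.39 with an estimated correlation). Gm6682, a predicted gene chosen after its values were seen, was at 20.09 and 10.12 CPM in the 10-week libraries labelled knockout and at 0 and 0.24 CPM in wild type.

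The lack of a VDR response at rest may be expected to lower vitamin D3-raised genes in knockout, and the values did not decide this: the smaller of both medians of those genes was 0.0135 on the log2 scale, with members going both ways.

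For the count of genes over both ages, the splits of the 8 fresh libraries that hold 2 libraries of each age on each side number 18, too few for a share under 0.05. In a model with age and the split as terms, but without sex or title series, the real split gave 44 genes, as the only 1 of these, and the highest other gave 3. The restriction to these splits was made after the counts had been seen. Of all 35 splits into 4 and 4, 2 gave as many: the other was the split by age, fitted without the age term, with 1717 genes, which points to the structure of the samples by age.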
